A study of Mus musculus with 12 samples.

How the data were processed

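Poly(A) RNA from pulverised frozen mouse forebrain was sequenced in 12 libraries, 3 each from females and males given PBS or the rAAV collagen domain construct. RNA was purified with TRIzol and a column kit with DNase, made into libraries with an Illumina TruSeq version 2 kit that does not keep strand, and read as pairs of 75 bp on a NextSeq 500, per the labels' protocols. The table deposited by the authors holds whole-number read counts per Ensembl gene ID, not normalised. STAR, DESeq2 and the GRCm39 genome build are named per the submitters' processing notes, with no role, version, counting tool, strand setting or annotation release. Whether the counting split reads among paralogs or pseudogenes is not stated. The table's 12 column names are the library names that the labels give for the 12 samples, and the columns were assigned by them.

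The table held 43629 gene IDs, of which 42462 were found among the GENCODE M21 names and took their symbols from there. The 1167 IDs not found held 0.144% of the reads and stayed in under their IDs, and 12311 IDs had no read in any library. The annotation available for names is of the GRCm38 build, so no coordinates are given. Totals ranged from 39272127 to 52323985 reads per library, and mitochondrially encoded genes held 7.37 to 9.86% of them. Chi-square values per degree of freedom between same-group libraries ranged from 13.1 to 114 over 12 pairs, so no library repeated another of its labelled group. Pairs across groups were not compared.

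Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 19145, and libraries were scaled by TMM. A quasi-likelihood F-test (estimateDisp and glmQLFit, both robust, common biological coefficient of variation 0.178) was used with two-sided p adjusted by Benjamini-Hochberg and a threshold of 0.05. Treatment in both sexes and male against female came from an additive fit of sex and treatment to all 12 libraries. Treatment within each sex and the interaction came from a fit of the 4 groups, which shares 1 estimate of the spread. CPM uses TMM-scaled library sizes, and values after ± are SDs between libraries. C1qtnf3 was also compared by a two-sided exact permutation test of log2(CPM + 1) within sexes.

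The models, thresholds, gene lists, alternatives (except those named below as later) and the rule for named genes were fixed before the data were examined. There were 41 gene lists, covering brain cell types, brain regions, immune responses, the secretory pathway, energy and translation, with 673 members, of which 6 symbols were not found. The 40 lists with 5 or more measured members (626 in all) were tested on log2 CPM (prior count 2) with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Camera sets a list against the other genes, while fry asks whether its genes move, on balance, one way. Named genes are C1qtnf3 in every library, the genes that passed, and, where few passed, those of smallest p up to 10 for treatment in both sexes, 5 within a sex, 3 for the interaction and 10 between the sexes, given as values. From each list described, up to 4 members of smallest p are named. App, Cst7 and Clec7a per library, the immunoglobulin genes and the members named in the fit of 7 libraries were chosen after their values were seen, as were all fits that leave out libraries by their C1qtnf3 or sex-linked reads or take a tissue covariate.

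The alternatives fixed beforehand were DESeq2 1.42.0 (Wald test), limma-voom, relative log expression factors, no filter, a filter of 1 CPM in 6 libraries, a threshold of 0.1, a replicate block, each library left out in turn, no sex term, averaged sex-specific effects, 1 surrogate variable from sva 3.50.0, and fits of 1 sex or 1 treatment alone. A library was taken to go against its treatment label where a collagen domain library had under 1000 C1qtnf3 reads or a PBS library had 1000 or more, and against its sex label by which of Xist and Ddx3y was higher.

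Simulated data with correct labels were used to test treatment in both sexes and in females, the interaction, male against female, and the list step. The contrast within males was not simulated, and genes were drawn independently, so camera's preset correlation was not tested. Counts were drawn from the real means and library sizes, with genes changed by factors of 1.5, 2 and 4. For treatment in both sexes edgeR recovered 54.5, 83.6 and 92.5% of these among 18982 genes with 9 false calls, and DESeq2 63.6, 88.1 and 94.0% with 33 false calls. Within females edgeR recovered 30.3, 61.2 and 89.6% among 18955 genes, and between the sexes 47.0, 74.6 and 97.0% among 18976. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Intervals and floors from read numbers would cover counting error only, and none was used in a test.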

Results

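Brain RNA was sequenced in 12 mouse libraries, 3 for each combination of treatment and sex. As newborns the mice had received PBS, or a recombinant adeno-associated virus (rAAV, a gene delivery vector) encoding a collagen domain construct, into the cerebral ventricles. Tissue was taken at 3 months of age. The series title names the collagen domain of C1qTNF3, a secreted protein of the C1q/TNF family. The comparison asks how the brain transcriptome differed between mice given this vector and mice given PBS. No group received an rAAV without the construct, so effects of the vector and of the construct cannot be told apart. Libraries held between 39272127 and 52323985 counted reads, with 24489 to 25284 genes detected at 1 read or more. Labels number the samples within a group but do not say that each came from a separate mouse, so all p-values measure only the spread between these libraries.

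C1qtnf3 (ENSMUSG00000058914), the mouse gene of the protein named in the title, was read in every library first as a check of the treatment labels. Among the 6 libraries labelled collagen domain, 4 held between 2612 and 4966 C1qtnf3 reads. The libraries labelled collagen domain female 1 and collagen domain female 3 held 23 and 8 reads (0.533 and 0.186 CPM). Among the 6 labelled PBS, 4 held between 12 and 28 reads, while PBS female 2 held 1071 and PBS male 1 held 2675 (22.3 and 59.1 CPM). The 6 libraries with many reads thus lay between 22.3 and 107 CPM and the other 6 between 0.186 and 0.706 CPM. By label the mean was 13.9 ± 23.8 CPM with PBS and 54.0 ± 44.8 CPM with collagen domain (SD, n = 6 each). The edgeR log2 fold change was 2.03 (SE 1.55, adjusted p = 1). A two-sided exact permutation test within sexes gave p = 0.11 (400 arrangements, n = 6 libraries per treatment). Leaving out 1 library moved the fold change between 0.15, without collagen domain female 2, and 3.67, without PBS male 1. Whether reads of the construct were counted on this gene is not stated, since the labels give no construct sequence.

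Sex-linked genes were read as a check of the sex labels. Xist, the RNA that silences 1 X chromosome in females, lay between 458 and 646 CPM in 6 libraries and between 0.34 and 3.6 CPM in the other 6. Ddx3y, a Y-linked RNA helicase gene, lay between 84.1 and 92.9 CPM where Xist was low and between 0.0221 and 0.324 CPM where Xist was high. PBS female 2 and collagen domain female 1 carried the low Xist and high Ddx3y level, at 0.937 and 0.579 CPM of Xist against 86.8 and 86.4 CPM of Ddx3y. PBS male 1 and collagen domain male 3 carried the reverse, at 646 and 582 CPM of Xist against 0.0221 and 0.0222 CPM of Ddx3y. In all, 4 libraries went against their treatment label, 4 against their sex label, 3 against both, and 5 against either, so every direction given by label below rests on labels that the reads contradict in 5 of 12 libraries.

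**Figure D1:**
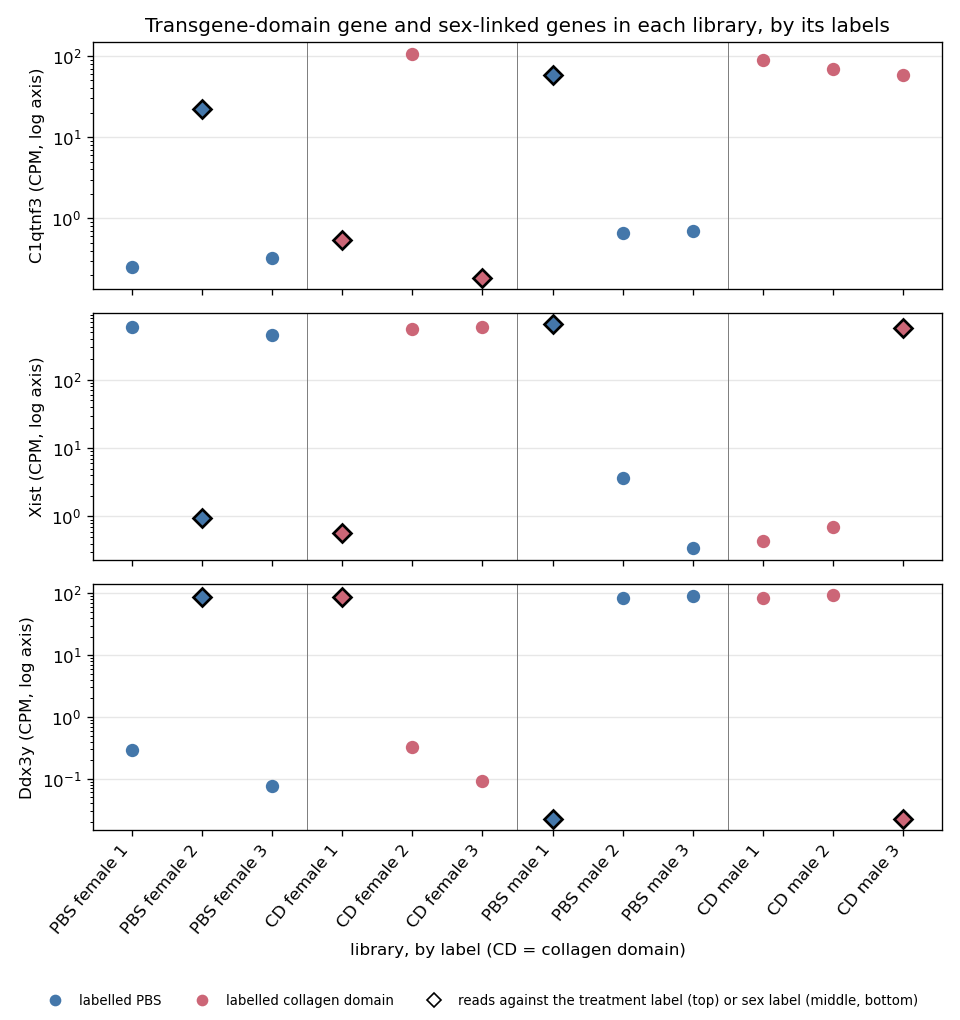
C1qtnf3, Xist and Ddx3y in CPM on log axes, 1 point per library, set out by the group on its label. C1qtnf3 lies at 22.3 to 107 CPM in 6 libraries and at 0.186 to 0.706 CPM in the other 6, and in 4 libraries this goes against the treatment label.

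With the libraries compared as labelled, no single gene passed. Camera at its preset correlation called gene groups of particular brain regions and of the energy and translation machinery, with small median differences. Of 100 splits of these libraries, the labelled one included, 89 called at least as many lists. Rises and falls of lists between treatments below are therefore differences by label, not shown effects of treatment. Hypothalamic genes rose in libraries labelled collagen domain, by a median of 0.41 on the log2 scale with 17 of 17 measured members above 0 (camera in limma, adjusted p = 5.58e-08; adjusted p = 0.97 with an estimated correlation). Its members of smallest p were Avp, the vasopressin gene, at 1.16 (SE 0.387), Pomc, the precursor of melanocortins and beta-endorphin, at 0.78 (SE 0.348), Hdc, which makes histamine, at 0.41 (SE 0.221), and Cartpt at 0.38 (SE 0.163). Choroid plexus genes rose by a median of 0.33, with 15 of 15 members above 0 (adjusted p = 2.66e-05; adjusted p = 0.97 with an estimated correlation). Sostdc1 stood at 0.60 (SE 0.235), Calml4 at 0.51 (SE 0.238), Kcne2, a potassium channel subunit, at 0.50 (SE 0.302), and Ttr, the thyroxine carrier transthyretin, at 0.37 (SE 0.228). Striatal genes rose by a median of 0.12, with 14 of 15 members above 0 (adjusted p = 0.00742; adjusted p = 0.97 with an estimated correlation), among them Drd2, a dopamine receptor, at 0.16 (SE 0.091) and Syndig1l at 0.22 (SE 0.0898).

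A further set of groups went the other way in the same comparison. Nuclear genes of oxidative phosphorylation fell by a median of 0.14, with 0 of 24 members above 0 (camera, adjusted p = 0.00037; adjusted p = 0.97 with an estimated correlation). Ndufb3, of complex I, stood at -0.17 (SE 0.133), and Ndufa4, of the respiratory chain, at -0.28 (SE 0.219). Cytosolic ribosomal protein genes fell by a median of 0.15, with 0 of 24 above 0 (adjusted p = 0.000694; adjusted p = 0.97 with an estimated correlation), with Rpl5 at -0.14 (SE 0.116) and Rpl32 at -0.30 (SE 0.246). Erythroid genes fell by a median of 0.08, with 2 of 9 above 0 (adjusted p = 0.0416; adjusted p = 0.97 with an estimated correlation). The haemoglobin genes Hbb-bt and Hbb-bs stood at -0.32 (SE 0.134) and -0.30 (SE 0.138), while Slc4a1, the red cell anion exchanger, stood at 0.69 (SE 0.457). Ribosomal protein genes have near-identical pseudogenes and the haemoglobin genes near-identical paralogs, so their single-gene values are uncertain.

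The other lists described here did not pass camera for treatment in both sexes. Activated microglia genes had a median of -0.11 (camera, adjusted p = 0.0794), with Cst7, a cystatin, at -2.70 (SE 1.23) and Clec7a, a pattern receptor, at -0.99 (SE 0.562). Cst7 stood at 7.82 CPM in PBS male 3 and between 0.0232 and 0.326 CPM in the other 11 libraries, and Clec7a at 2.98 CPM in PBS male 3 and at most 0.606 CPM elsewhere. Homeostatic microglia genes had a median of -0.04 (adjusted p = 0.427), complement genes -0.01 (adjusted p = 0.914), reactive astrocyte genes 0.06 (adjusted p = 0.892) and interferon-stimulated genes -0.05 (adjusted p = 0.202). Genes of collagen folding and secretion had a median of 0.07 (adjusted p = 0.102), with P3h1, a prolyl hydroxylase of collagen, at 0.15 (SE 0.0768). Genes of ER stress had a median of 0.04 (adjusted p = 0.0794), with Hspa5, the chaperone BiP, at 0.11 (SE 0.0653). The C1q/TNF family and its adiponectin receptors, without C1qtnf3, had a median of 0.02 (adjusted p = 0.987). Border macrophage and infiltrating myeloid genes held the 2 members that passed when p was adjusted over the list alone, Pf4 at -0.76 (SE 0.206) and Ly6c2 at -0.88 (SE 0.261), against 0 of 626 list members past the threshold over all genes tested.

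**Figure D2:**
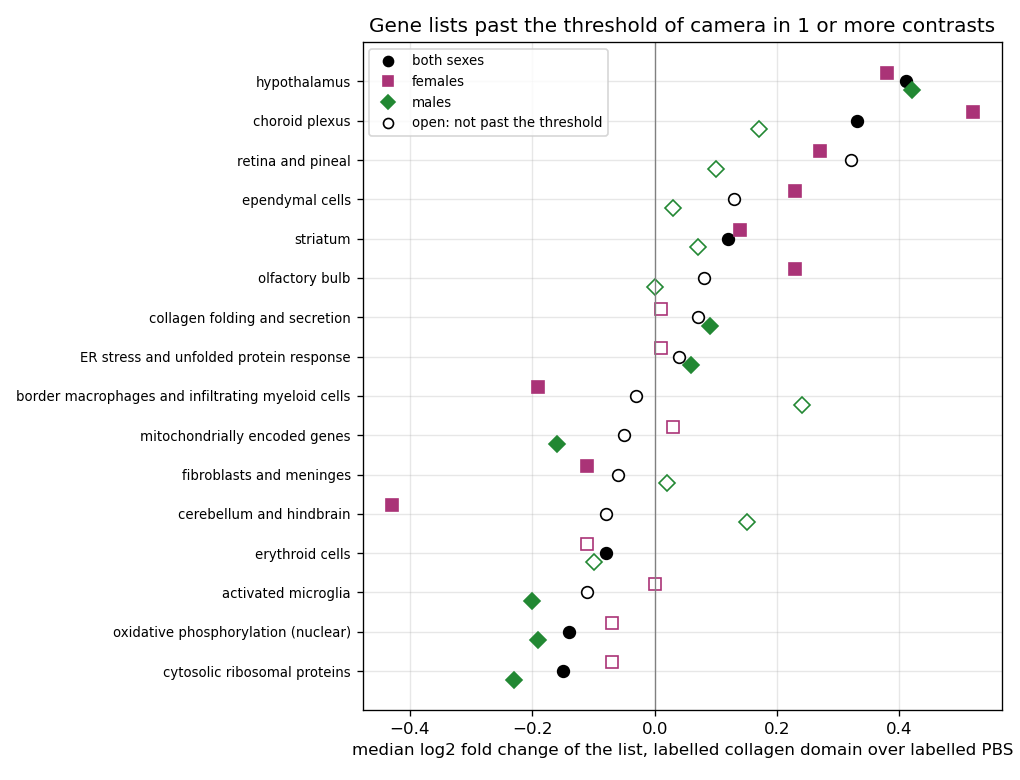
Median log2 fold change, collagen domain over PBS as labelled, of the gene lists that passed camera in 1 or more contrasts, for both sexes and within each sex. The hypothalamus list sits at 0.41 and the choroid plexus list at 0.33 in both sexes, and the list of nuclear oxidative phosphorylation genes at -0.14.

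Gene by gene, edgeR called 0 of 19145 genes between the labelled treatments, with 354 at an unadjusted p under 0.05 where 957 were expected by chance, and DESeq2 and limma-voom also called 0. The 10 genes of smallest p all had an edgeR adjusted p of 1. Among them, Col22a1, a collagen gene of tissue junctions, stood at -0.62 (SE 0.126), at 2.40 ± 0.16 CPM with PBS and 1.57 ± 0.304 CPM with collagen domain (SD, n = 6 libraries each). Gpr179, an orphan receptor gene of retinal bipolar cells, stood at 0.96 (SE 0.228), at 15.8 ± 2.88 against 32.1 ± 15.8 CPM. Slc17a8, the vesicular glutamate transporter VGLUT3, stood at 0.33 (SE 0.0852), at 4.70 ± 0.319 against 5.90 ± 0.618 CPM. Rtp1, an olfactory receptor transporter, stood at -0.76 (SE 0.191) and the cilium gene Tekt4 at -0.56 (SE 0.145). The complement protease gene C1s2 stood at 1.04 (SE 0.267), the chemokine receptor gene Ccr10 at 0.58 (SE 0.144), Tns4 at 0.96 (SE 0.234), Mybl2, a regulator of the cell cycle, at 0.76 (SE 0.2), and Gm38366 at 1.73 (SE 0.413). On simulated data of this design, edgeR recovered 83.6% of genes changed by a factor of 2 and 54.5% of those changed by 1.5. The simulated labels were correct, while the reads here contradict the treatment label in 4 of 12 libraries. Simulated genes also varied independently, while cerebellum and hindbrain genes here differed together between libraries, so these shares may not hold for the real data.

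Camera called 6 of 40 lists, against 0 with an estimated correlation and 0 with fry, while 19 of the 626 members had an unadjusted p under 0.05. The hypothalamus call held without any 1 library, with medians from 0.26, without collagen domain male 3, to 0.51. The choroid plexus call held too, with medians from 0.14, without PBS female 1 (adjusted p = 0.0321), to 0.50, without PBS female 3 or collagen domain male 1. The call of oxidative phosphorylation ended without PBS male 3 and stood at -0.05 (adjusted p = 0.0479) without PBS female 1, and that of the ribosome ended without PBS female 1, collagen domain female 2, PBS male 3 or collagen domain male 2. PBS female 1 and PBS male 3 also held the highest shares of mitochondrially encoded reads, 9.86 and 9.67%, against 7.37 to 8.83% in the other 10 libraries. The striatum call ended without PBS female 3, collagen domain female 1 or 3, PBS male 3, or collagen domain male 1 or 3. The erythroid call held only without PBS female 1, collagen domain female 1, PBS male 1 or collagen domain male 2, and with all 12.

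When the 5 libraries whose reads went against a label were left out, an alternative chosen after the data were seen, 7 libraries remained, 4 labelled PBS and 3 labelled collagen domain. Here edgeR called 2 genes, both higher with collagen domain, and 1091 genes had an unadjusted p under 0.05 where 957 were expected. C1qtnf3 had a log2 fold change of 7.54 (SE 0.328, adjusted p = 0.000698, against 0.000315 to 1 over its other alternatives), but the libraries were left out by their C1qtnf3 reads, so this separation follows from the choice. Igkv3-12 (ENSMUSG00000094117), an immunoglobulin kappa variable gene, was the other. It had 54, 36 and 42 reads in collagen domain female 2, male 1 and male 2, and 1 read in PBS female 3 and 0 in the remaining PBS libraries of these 7. Over all 12 libraries it had 13 to 54 reads where C1qtnf3 had 1000 or more and 0 to 1 elsewhere, so the choice of libraries favours this call too. The Igkv3-12 call ended with PBS male 3 also left out, or with a covariate of cerebellum and hindbrain genes. Ribosomal protein and oxidative phosphorylation genes passed downward with camera in these 7 libraries, at adjusted p = 1.35e-09 and 6.04e-05, and both at adjusted p = 0.93 with an estimated correlation. Immediate early genes, which neurons switch on with activity, also fell there, by a median of 0.46 (adjusted p = 4.43e-06; adjusted p = 0.93 with an estimated correlation), with Btg2 at -0.88 (SE 0.0974), Npas4 at -1.88 (SE 0.357) and Fos at -1.15 (SE 0.288). Endothelial genes rose (adjusted p = 0.00105; adjusted p = 0.93 with an estimated correlation), with Flt1, a VEGF receptor, at 0.53 (SE 0.151) and the tight junction gene Cldn5 at 0.31 (SE 0.0938). Genes of collagen folding rose too (adjusted p = 0.0462; adjusted p = 0.93 with an estimated correlation). Over all 12 libraries, immediate early genes had a median of -0.05 with 7 of 19 above 0 (camera, adjusted p = 0.442). Endothelial genes had a median of 0.05 there (camera, adjusted p = 0.177). The hypothalamus (median 0.20, adjusted p = 0.511), choroid plexus (0.23 with 15 of 15 above 0, adjusted p = 0.384), striatum (-0.08, adjusted p = 0.698) and erythroid (-0.12, adjusted p = 0.119) calls ended in these 7 libraries. Without the 4 libraries against their treatment label alone, hypothalamic genes still passed upward (median 0.35, 15 of 17 above 0, adjusted p = 0.0237; adjusted p = 0.871 with an estimated correlation).

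Between libraries labelled female, choroid plexus genes rose with collagen domain by a median of 0.52, with 15 of 15 above 0 (camera, adjusted p = 3.16e-09; adjusted p = 0.786 with an estimated correlation). Calml4 stood at 0.85 (SE 0.326), Ttr at 0.66 (SE 0.31) and the water channel gene Aqp1 at 0.35 (SE 0.168). Hypothalamic genes rose by a median of 0.38 (adjusted p = 2.82e-05; adjusted p = 0.786 with an estimated correlation), with Avp at 1.32 (SE 0.569) and Crh, the releasing hormone of the stress axis, at 0.38 (SE 0.17). Ependymal genes rose by a median of 0.23 (adjusted p = 0.00651), striatal genes by 0.14 (adjusted p = 0.00566) and olfactory bulb genes by 0.23 (adjusted p = 0.0415), each at adjusted p = 0.99 with an estimated correlation. Genes of retina and pineal rose by a median of 0.27 (adjusted p = 0.0344; adjusted p = 0.786 with an estimated correlation). With 1 library left out, the median ranged from 0.09 to 0.39 for ependymal and from 0 to 0.32 for striatal genes. It ranged from 0.06 to 0.52 for olfactory bulb and from 0.07 to 0.43 for retina and pineal genes. Border macrophage genes fell by a median of 0.19 (adjusted p = 0.0208; adjusted p = 0.526 with an estimated correlation), with Pf4 at -0.87 (SE 0.297). Their median ranged from -0.24 to -0.02 with 1 library left out. Fibroblast and meningeal genes fell by a median of 0.11 (adjusted p = 0.0415) and cerebellum and hindbrain genes by 0.43 (adjusted p = 0.0344), both at adjusted p = 0.99 with an estimated correlation. With 1 library left out, the fibroblast median ranged from -0.26, without collagen domain female 2, to 0.02, without collagen domain female 1, and the hindbrain median from -4.08, without collagen domain female 2, to 0.23, without PBS female 2. Their direction also turned without the 4 libraries against their treatment label, where fibroblast and meningeal genes stood 0.22 higher (adjusted p = 0.014) and cerebellum and hindbrain genes 2.52 higher (adjusted p = 0.00868), at adjusted p = 0.785 and 0.817 with an estimated correlation. Without the 5 against either label they were again higher, at adjusted p = 0.0193 and 0.00742, both at adjusted p = 0.871 with an estimated correlation, and only 1 female collagen domain library remained in both cases. Striatal genes turned to -0.11 with 3 of 15 above 0 and no longer passed (adjusted p = 0.476 without the 4 and 0.428 without the 5), and the hypothalamus call ended without the 4 (adjusted p = 0.0699) but not without the 5 (adjusted p = 0.0202; adjusted p = 0.871 with an estimated correlation). Ependymal, olfactory bulb, retina and border macrophage lists were not called in either case, while choroid plexus genes were (adjusted p = 0.000412 and 0.000375; adjusted p = 0.817 and 0.871 with an estimated correlation).

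The cerebellum and hindbrain genes differed far more between single libraries than between labelled treatments. Their mean log2 CPM lay 2.17 to 3.00 above the mean of all 12 in PBS female 2, PBS female 3, collagen domain female 2, PBS male 3 and collagen domain male 2. It lay 2.48 above in PBS female 2 and at -2.25 in collagen domain female 1, both of which went against their labels. The choroid plexus call in females ended without PBS female 1 (median 0.14, adjusted p = 0.0601), and the hypothalamus call held without any 1 library. Gene by gene, edgeR called 0 of 19145 genes in females (3 libraries against 3), with 280 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Adjusted over the list alone, 0 of the 626 list members passed. The genes of smallest p, each at an edgeR adjusted p of 1, were Tns4 at 1.36 (SE 0.304), Gm38366 at 2.35 (SE 0.566), Tarbp1, an RNA methyltransferase gene, at 0.49 (SE 0.117), Rtp1 at -1.01 (SE 0.261) and Rpl29-ps5, a ribosomal pseudogene, at -4.56 (SE 1.25). C1qtnf3 stood at 2.24 (SE 2.35), at 7.62 ± 12.7 CPM with PBS and 36.0 ± 61.7 CPM with collagen domain (SD, n = 3 libraries each).

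Between libraries labelled male, hypothalamic genes rose with collagen domain by a median of 0.42, with 17 of 17 above 0 (camera, adjusted p = 0.000265; adjusted p = 0.962 with an estimated correlation). Hcrt, the orexin gene, stood at 1.05 (SE 0.442) and Oxt, the oxytocin gene, at 1.28 (SE 0.816). Genes of ER stress rose by a median of 0.06, with 21 of 27 above 0 (adjusted p = 0.0184; adjusted p = 0.957 with an estimated correlation), among them Hspa5 at 0.18 (SE 0.0919) and Pdia4, a disulfide isomerase, at 0.15 (SE 0.0889). Genes of collagen folding and secretion rose by a median of 0.09, with 19 of 22 above 0 (adjusted p = 0.0371; adjusted p = 0.962 with an estimated correlation), among them Plod3, a collagen lysyl hydroxylase, at 0.26 (SE 0.105). The collagen folding call ended without PBS male 2 or 3 or collagen domain male 2 or 3, and its median was 0.02 without collagen domain male 2. Ribosomal protein genes fell by a median of 0.23 with 0 of 24 above 0 (adjusted p = 0.000149), mitochondrially encoded genes by 0.16 with 0 of 13 above 0 (adjusted p = 0.00023) and nuclear oxidative phosphorylation genes by 0.19 (adjusted p = 0.00121). Each of these stood at adjusted p = 0.962 with an estimated correlation. Among the mitochondrial genes, mt-Atp6 stood at -0.18 (SE 0.0996) and mt-Co1 at -0.18 (SE 0.111), and near-identical nuclear copies make these single values uncertain.

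Activated microglia genes fell between the same libraries by a median of 0.20, with 3 of 20 above 0 (camera, adjusted p = 0.03; adjusted p = 0.962 with an estimated correlation). Cst7 stood at -3.58 (SE 1.45), the chemokine gene Ccl6 at -1.32 (SE 0.64) and the lysosomal gene Cd68 at -0.38 (SE 0.213). PBS male 3 alone held 299 Cst7 reads (7.82 CPM) and 114 Clec7a reads (2.98 CPM), against at most 14 and 26 reads in any other library. Without PBS male 3 the calls of activated microglia, ribosomal, mitochondrially encoded and oxidative phosphorylation genes all ended. The activated microglia and oxidative phosphorylation calls also ended without collagen domain male 1, and the hypothalamus call ended without PBS male 1 or collagen domain male 3, both against a label. Without collagen domain male 3 alone, the hypothalamus median fell from 0.42 to 0.04. The hypothalamus call also ended without the 4 libraries against their treatment label (median 0.31, adjusted p = 0.0746), and turned without the 5 against either label (median -0.11, 5 of 17 above 0, adjusted p = 0.673). Gene by gene, edgeR called 0 of 19145 genes in males (3 libraries against 3), with 325 at an unadjusted p under 0.05. DESeq2 called 3, all lower with collagen domain, and limma-voom called 0. Those 3 were Gm15631, at 6.87 ± 1.48 CPM with PBS and 2.90 ± 0.486 with collagen domain (edgeR log2 fold change -1.24, SE 0.195, adjusted p = 0.889), A830036E02Rik at -4.66 (SE 0.966), and Hif3a, a hypoxia-inducible factor subunit, at -0.91 (SE 0.175). Rdm1 stood at -0.90 (SE 0.194) and Gm14418 at -0.78 (SE 0.17), all except Gm15631 at an edgeR adjusted p of 1. C1qtnf3 stood at 1.83 (SE 2.28), at 20.2 ± 33.7 CPM with PBS and 71.9 ± 15.3 CPM with collagen domain (SD, n = 3 libraries each), and 0 of 626 list members passed adjusted over the list alone.

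Whether the treatment difference itself differed between the sexes was tested as an interaction. With edgeR, 0 of 19145 genes passed, with 263 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom called 0. The DESeq2 call was Gm15631, whose mean with PBS was 4.38 ± 0.87 CPM in females and 6.87 ± 1.48 in males, against 5.75 ± 0.324 and 2.90 ± 0.486 with collagen domain (edgeR log2 difference -1.64, SE 0.273, adjusted p = 1). Cyp2j13, a cytochrome P450 gene, stood at -3.45 (SE 0.623) and Agr3 at -4.34 (SE 1.09), both at an edgeR adjusted p of 1 and under 1 CPM in every group mean. Camera called 7 of 40 lists, against 0 with an estimated correlation and 0 with fry, and 0 of 626 members passed adjusted over the list alone. Choroid plexus genes had a median difference of -0.40, lower in males with 1 of 15 above 0 (adjusted p = 0.00132; adjusted p = 0.877 with an estimated correlation). The call ended with a smaller median difference without PBS female 1 (median -0.03, camera adjusted p = 0.526) or collagen domain male 1 (-0.21, adjusted p = 0.203). It also ended without PBS male 2, where the median stayed close to -0.40 (-0.39, adjusted p = 0.137). Simulated data of this contrast, with correct labels and independent genes, gave edgeR calls for 40.3% of genes changed by a factor of 2 and 83.6% of those changed by 4.

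Between libraries labelled male and female, camera at its preset correlation called microglial and erythroid genes higher and meningeal genes lower in those labelled male. The sex-linked reads of 4 libraries went against these labels, and no list passed with an estimated correlation. The list calls were not compared with other splits of the libraries. Rises and falls here are therefore differences by label, not shown effects of sex. Homeostatic microglia genes rose by a median of 0.16, with 13 of 14 above 0 (camera, adjusted p = 5.58e-09; adjusted p = 0.082 with an estimated correlation), among them P2ry12, a purine receptor, at 0.18 (SE 0.0608). Activated microglia genes rose by a median of 0.16 (adjusted p = 6.23e-05; adjusted p = 0.527 with an estimated correlation), with Lyz2 at 0.76 (SE 0.206) and Cst7 at 3.15 (SE 1.24). The list's mean lay 1.12 above that of all 12 libraries in PBS male 3, and without that library its call ended (median 0.08, adjusted p = 0.11). Complement genes rose by a median of 0.18 (adjusted p = 0.0112; adjusted p = 0.437 with an estimated correlation), with C5ar1, an anaphylatoxin receptor, at 0.92 (SE 0.234) and C1qa at 0.28 (SE 0.114), and this call ended without PBS male 3 (adjusted p = 0.0869) or PBS female 1 (adjusted p = 0.162). Erythroid genes rose by a median of 0.42, with 8 of 9 above 0 (adjusted p = 5.68e-10; adjusted p = 0.082 with an estimated correlation), and Hbb-bs stood at 179 ± 37.5 CPM in females and 282 ± 54.8 in males (SD, n = 6 libraries each). Fibroblast and meningeal genes fell by a median of 0.30, with 1 of 16 above 0 (adjusted p = 1.56e-13; adjusted p = 0.082 with an estimated correlation), with Ogn, a small proteoglycan, at -0.37 (SE 0.0869) and Fmod at -0.48 (SE 0.156). The C1q/TNF family fell by a median of 0.07, with 1 of 16 above 0 (adjusted p = 0.00287; adjusted p = 0.082 with an estimated correlation), with C1qtnf6 at -0.35 (SE 0.114).

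Sex-linked genes did not pass between the labelled sexes, where 4 libraries went against the label. Xist stood at -0.83 (SE 1.98), at 366 ± 287 CPM in females and 205 ± 317 in males, and Ddx3y at 1.02 (SE 1.78), both at an edgeR adjusted p of 1. Gm11942 had the smallest p, at 1.56 ± 0.496 CPM in females and 28.4 ± 14.4 in males (log2 fold change 4.10, SE 0.575, adjusted p = 0.331). Next stood Irgc1 at -1.75 (SE 0.313), Exoc3l2 at -1.51 (SE 0.277), 9330104G04Rik at 0.73 (SE 0.137), Gm17511 at 2.59 (SE 0.51), the calcium channel subunit gene Cacng6 at -1.60 (SE 0.315), Stat6 at -0.36 (SE 0.078) and Hbb-bt at 0.61 (SE 0.135). With edgeR, 0 of 19145 genes passed, with 377 at an unadjusted p under 0.05, while DESeq2 called 8 and limma-voom 0. Adjusted over the list alone, 8 of the 626 list members passed, 5 of them erythroid, 2 meningeal and C5ar1, against 0 over all genes tested. Camera called 16 of 40 lists, 8 in each direction, against 0 with an estimated correlation and 0 with directional fry. The mixed form of fry, which counts moves in either direction, called 1, complement genes (adjusted p = 0.0422). Directional fry called 3 lists without the 4 libraries against their treatment label and 4 without the 5 against either label. Fibroblast and meningeal genes (fry adjusted p = 0.0138 and 0.0308), ER stress genes (0.0138 and 0.0292) and the C1q/TNF family (0.0184 and 0.0445) passed in both. All 3 were lower in libraries labelled male. Without the 4, these still included collagen domain male 3, whose sex-linked reads went against that label. The 4 or 5 libraries were left out for their reads after the data were seen, and 0 lists passed camera with an estimated correlation in either case. Without PBS male 3, edgeR called 5 genes between the labelled sexes, Gm11942 at 4.40 (adjusted p = 1.33e-05), Cacng6, Gm17511, 9330104G04Rik and Exoc3l2. Gm11942 lay between 27.3 and 42.4 CPM in the 5 other libraries labelled male, PBS male 1 and collagen domain male 3 included, between 0.907 and 2.21 CPM in the 6 labelled female, and at 1.78 CPM in PBS male 3. Without the 5 libraries against a label it called 7, with Kdm5d, Ddx3y, Uty, Eif2s3y, Cldn34c1 and Cldn34c2 higher and Xist lower in males, but these libraries were left out by Xist and Ddx3y themselves. Cldn34c1 was also called without the 4 libraries against their treatment label (edgeR log2 fold change 7.92, adjusted p = 0.00145). That fit counts collagen domain male 3 as male.

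**Figure D3:**
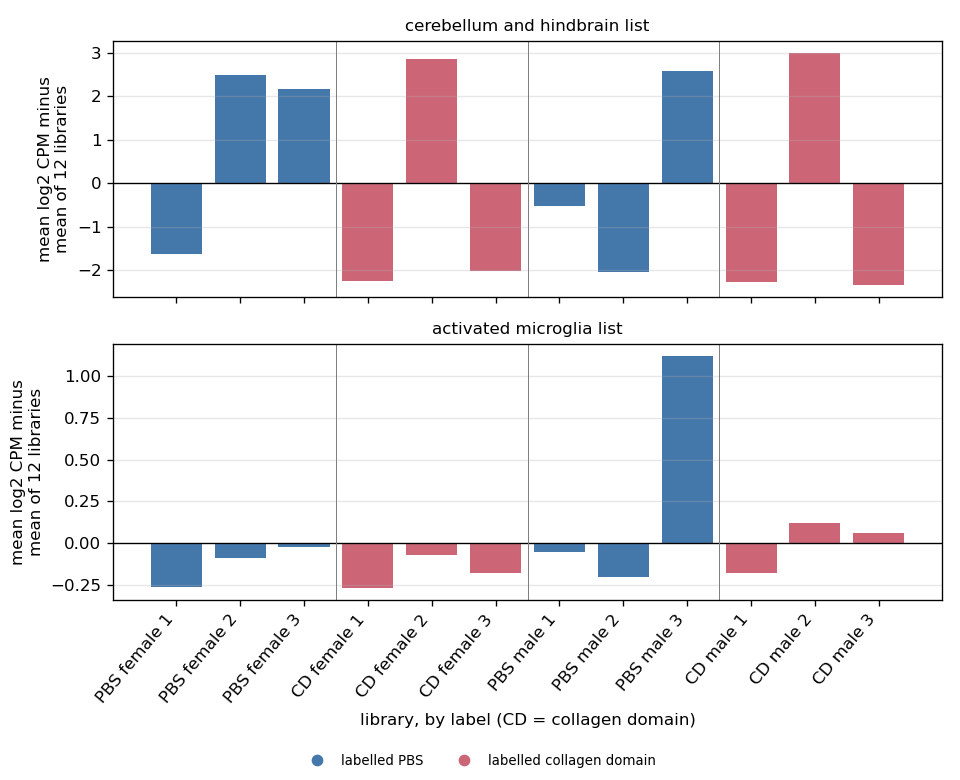
Mean log2 CPM of gene lists per library, minus the mean of all 12 libraries, with 1 bar per library ordered by the group on its label. The cerebellum and hindbrain list lies 2.17 to 3.00 above the mean in 5 libraries, and the activated microglia list 1.12 above it in PBS male 3.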

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

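The comparisons with other splits of the libraries and the brainstem and forebrain panels were chosen before the values they measure were seen, and all other tests in this part were chosen only after the result was seen.

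Single libraries stood apart from the other 5 of their labelled treatment in 5 of 104 groups of 6 tested, by their gap relative to the range, and chance gives about 1 in 20, or 5.2 here. PBS male 3 lay 1.21 above the median of the others in activated microglia genes, on the scale of mean log2 CPM, and at -0.27 in both glutamatergic neuron and cortical layer genes. PBS male 2 lay at -0.26 in hippocampal genes, and collagen domain female 2 at -0.35 in homeostatic microglia genes.

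Camera on the interaction called 7 gene lists, none of which passed with an estimated correlation, at adjusted p = 0.675 for border macrophage genes and adjusted p = 0.877 for the other 6. Choroid plexus genes stood at a median of -0.40 (male minus female difference, adjusted p = 0.00132), with Ttr at -0.59 (SE 0.437), and ependymal genes at -0.23 (adjusted p = 0.0282), with Cfap126 at -0.95 (SE 0.279). Border macrophage genes stood at 0.39 (adjusted p = 0.0282), with Lyve1 at 0.72 (SE 0.314), and astrocyte genes at 0.12 (adjusted p = 0.0282), with Ntsr2 at 0.43 (SE 0.147). Thalamic genes stood at -0.39 (adjusted p = 0.0282), with Rgs16 at -0.39 (SE 0.196), mitochondrially encoded genes at -0.20 (adjusted p = 0.00132) and ribosomal protein genes at -0.16 (adjusted p = 0.0282). Each of the 7 calls ended without at least 1 of the 12 libraries, and astrocyte and ribosomal protein genes turned to -0.15 and 0.19 without the 4 libraries against their treatment label (adjusted p = 0.305 and 0.0645).

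The first pattern is the conflict between reads and labels in PBS female 2, PBS male 1, collagen domain female 1, collagen domain female 3 and collagen domain male 3. Mixing of reads or RNA with a library of the opposite Xist and Ddx3y state was argued against. In the 4 libraries against their sex label the weaker of Xist and Ddx3y reached at most 0.204% of its lowest level elsewhere as the stronger one. Mixing between libraries alike in these 2 genes was not tested. PBS female 2 held 22.3 CPM of C1qtnf3, against 57.9 to 107 CPM in the other libraries with many C1qtnf3 reads. A wrong or failed injection of correctly labelled mice was argued against for 3 libraries, since these 3 of the 4 against their treatment label also went against their sex label, while for collagen domain female 3, with 8 C1qtnf3 reads and sex-linked reads that matched its label, it cannot be told apart from a wrong label. An exchange of labels among these libraries may account for the C1qtnf3 and sex-linked reads: 5 of 5 carried a combination of C1qtnf3 and sex-linked reads that belonged to another of the same 5 labels, matched 1 to 1. Gm11942 and 4 other genes went with the sex label in the 4 libraries against their sex label, which an exchange leaves unexplained. Gm11942 stood at 27.8 and 32.5 CPM in PBS male 1 and collagen domain male 3. It stood at most at 1.92 CPM in PBS female 2 and collagen domain female 1. The 5 genes passed edgeR without PBS male 3, and DESeq2 with all 12 libraries (Gm11942 adjusted p = 2.03e-09, the other 4 at most 0.00208). In the 6 libraries labelled collagen domain alone, edgeR also called Gm11942 (log2 fold change 4.67, adjusted p = 0.0107). All 5 were picked for following the sex label, so the exchange stays open and no library was given another label.

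The second pattern is the high level of cerebellum and hindbrain genes in 5 libraries, PBS female 2, PBS female 3, collagen domain female 2, PBS male 3 and collagen domain male 2. Sequencing depth was argued against, with 3 of the 5 totals inside the range of the other 7, and so was the treatment, with 2 of these libraries labelled PBS and holding reads that went with their labels (3 of 6 PBS and 2 of 6 collagen domain libraries, two-sided Fisher's exact p = 1). Hindbrain tissue left in the dissected piece may be the source: a separate brainstem panel of 12 measured genes was higher in 5 of 5 (means -0.05 to 1.15) than in any of the other 7 (-3.79 to -0.32), and 14 of 16 forebrain panel genes were lower, by a median of -0.26 (SD 0.593). PBS male 1, at -0.32 on the brainstem panel, lay close to the 5.

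The third pattern is the high level of activated microglia genes in PBS male 3, where 16 of 20 members lay above all other libraries, at a median log2 ratio of 0.86 (SD 1.34). More microglia were argued against as the whole cause, since homeostatic microglia genes stood at a median of 0.21 (SD 0.346), and infiltrating blood cells were too, with lymphocyte and myeloid genes at 0.01 (SD 0.553, 21 members). An App transgene or amyloid-model genotype may lie behind it: App stood at 2520 CPM against 1270 to 1510 in the others (log2 ratio 0.89), rank 13 of 2193 abundant genes, while Aplp1 stood at -0.19, Aplp2 at -0.03 and Prnp at 0.10. Labels give no genotype, so no biological group could be tested.

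Other splits of the same libraries were fitted in the same way, with treatment labels redrawn within each sex, or sex labels within each treatment for male against female. The labelled split itself is counted among the 100 splits, and among the 10 within a sex. Of the lists for treatment in both sexes, 89 of 100 splits gave as many as the real 6, the highest other giving 19, so chance could not be excluded. Where the real count was 0 genes, every split gives as many by construction, so these comparisons say nothing on chance: 100 of 100 for treatment in both sexes (highest other 2534), the interaction (3454) and male against female (1152), and 10 of 10 in females (2) and in males (6). Within a sex, 10 splits are too few for a share under 0.05, with 9 lists in females (as many in 9 of 10, highest other 15) and 7 in males (as many in 8 of 10, highest other 18). Splits that called many genes point to a structure of the libraries. Both treatment splits with all 5 libraries high in hindbrain genes on 1 side called genes, 1186 and 265, and the sex split with 1152 genes placed all 5 on 1 side too. The splits with 2534 and 3454 genes placed 4 of the 5 on 1 side, as did many that called 0, so the hindbrain genes do not mark those.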

How the results depend on the processing

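Alternatives that leave out the 4, 5 or 6 doubted libraries, or add a tissue covariate, were chosen after seeing the data, and the others before. Of the alternatives other than single left-out libraries, 11 of 15 kept the count of genes for treatment in both sexes, 9 of 13 in females, 8 of 13 in males, 11 of 12 for the interaction and 8 of 14 between sexes. The C1qtnf3 fold change kept its side of the threshold in 10 of 14, and the counts of lists were within 1.5 times in 6, 7 and 8 of 10 for both sexes, females and males. Without the 4 libraries against their treatment label, edgeR called 2 genes for treatment (C1qtnf3 7.43), 1 in females, 1 in males and 1 between sexes, and camera 12 lists, 8 higher and 4 lower. Without the 5 against either label it called 2 (C1qtnf3 7.54), 1, 1 and 7, and with the hindbrain covariate added 1 (C1qtnf3 7.55), 1, 2 and 6. Without these 5 and PBS male 3 it called 1 (C1qtnf3 7.79), 1, 1 and 6, and camera 12 lists, 7 higher and 5 lower. The libraries were left out by C1qtnf3 or sex-linked reads. This fixes the outcome of these genes and favours Igkv3-12, whose reads went with those of C1qtnf3. Females then keep 1 collagen domain library, assumed to vary like the other groups. DESeq2 called 3 genes in males, 1 for the interaction and 8 between sexes where edgeR called 0, and edgeR called 2 between sexes in the 6 collagen domain libraries alone. An estimated correlation and fry each gave 0 lists for both sexes, females and males, against 6, 9 and 7, and the hindbrain covariate gave 5 in females. The cause was not tested for these changes, except that camera's preset correlation lies below most estimated ones.

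With 1 library left out, lists numbered 2 (without PBS male 3) to 10 (without PBS female 1) for both sexes, 4 (without PBS female 2) to 12 in females, with 5 without collagen domain female 3, and 4 (without PBS male 3) to 11 (without collagen domain male 2) in males. Genes numbered 0 to 0 for treatment, in females and for the interaction, 0 to 1 in males (1 without collagen domain female 3) and 0 to 5 between sexes (5 without PBS male 3). C1qtnf3 ranged from 0.15 to 3.67. Single calls in females ended without PBS female 1 (choroid plexus, ependymal, border macrophage), PBS female 2 (ependymal, border macrophage, hindbrain, olfactory bulb, retina, fibroblast), PBS female 3 (striatum, hindbrain, olfactory bulb, retina, fibroblast), collagen domain female 1 (hindbrain, olfactory bulb, retina, fibroblast), collagen domain female 2 (border macrophage), collagen domain female 3 (ependymal, striatum, hindbrain, olfactory bulb, retina, fibroblast), PBS male 3 (fibroblast, olfactory bulb, retina), collagen domain male 1 (fibroblast, olfactory bulb) and collagen domain male 2 or 3 (fibroblast). Calls of ER stress in males ended without PBS male 2 or collagen domain male 1, and of collagen folding without PBS male 2 or 3 or collagen domain male 2 or 3.

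Same-numbered libraries of the treatments did not deviate together from their labelled group means (r from -0.38 to 0.44 over 6 pairs, 2 of 6 highest with their own number). The group means rest on labels that the reads contradict in 5 libraries, so pairing by number cannot be excluded. With a replicate block, edgeR called 0 genes in all 5 comparisons, C1qtnf3 stood at 3.07, and camera called 4, 7 and 8 lists for both sexes, females and males, so the block changed no count by over 1.5 times. Depth limits low genes such as Cst7, at 1 to 14 reads in 11 libraries.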

Other observations

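All tests in this part were chosen only after the result was seen. Immunoglobulin kappa variable genes Igkv3-12 and Igkv3-7 were read almost wholly in the libraries with many C1qtnf3 reads, whatever their label. Igkv3-12 had 13 to 54 reads in the 6 libraries with 1000 or more C1qtnf3 reads and 0 to 1 in the other 6, and Igkv3-7 had 12 to 42 against 0. Of 281 immunoglobulin variable genes in the table, these 2 were the ones with 10 or more reads in 3 or more libraries. They are near-identical paralogs, so the share of each is uncertain.

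A hypothesis is that these reads come from the same RNA as the C1qtnf3 reads, as a construct that joins the collagen domain to an antibody fragment may give, since the series title also names single-chain antibody fragments. Across the 6 libraries the log2 CPM of Igkv3-12 followed that of C1qtnf3 with Pearson's r = 0.958 (two-sided exact permutation p = 0.00833, adjusted 0.0167 over 2 relations) and Spearman's rho = 0.886 (exact permutation p = 0.0333, adjusted 0.0666). For Igkv3-7, r was 0.904 (exact permutation p = 0.0222, adjusted 0.0222) and rho 0.714 (exact permutation p = 0.136, adjusted 0.136). Without the 2 libraries farthest from the median C1qtnf3 level, r over 4 libraries was 0.546 and 0.236, so both relations rest on those 2. There were 1 to 1.42 Igkv3-12 reads per 100 C1qtnf3 reads. The construct's sequence was not used here, so its presence in the reads was not tested.

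Collagen domain female 1 stood out in another way, with 5050 CPM of the ribosomal RNA-like gene Gm42418 and 1840 CPM of Lars2, a mitochondrial tRNA synthetase gene. The other 11 libraries held 511 to 2950 and 148 to 780 CPM.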
